A study of Drosophila melanogaster with 3 samples.

How the data were processed

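The deposited data were peak lists of 3 ChIP-seq libraries from whole larvae, precipitated through GFP on the Noc protein, with fragments of 200 to 800 bp by sonication, per the labels. Per the text notes deposited beside the lists, each replicate list was made from the alignment of that library and a control alignment, the pooled list from all 3 libraries together and the same kind of control, and the IDR list from those 4 lists. Peaks were therefore called per library and on the pooled libraries. The assembly is dm6, per the labels, and the highest peak position on each chromosome lay within the length of the reference sequence used here. The peak caller, its settings and the aligner are not given in the sources used here. The control alignment was not analysed here. Each peak carries a score, the signal value, which is the authors' own value on a scale not given in the sources used here, and it was used only to rank, filter or describe peaks within a list. The −log10 q value that the authors deposited reaches a ceiling, at which all 7201 IDR peaks stand (4.27), so it was not used for ranking. Summits are the deposited offset plus the peak start. The replicate and pooled lists all end at 30000 peaks, and the IDR list was checked to be the 7201 peaks of the pooled list with the highest signal value. Of the IDR peaks, 403 repeat an interval with another summit, and no summit occurs more than once.

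Coordinates are 1-based on dm6. Genes, transcripts and transcription start sites (TSS) came from the Ensembl annotation of the same assembly and sequence from the RefSeq copy of it, for the chromosome arms 2L, 2R, 3L, 3R, 4 and X, with transposons left out. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The main tests, gene lists, motifs, the rule for named genes and most alternatives were fixed before the data were examined.

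Replicate lists were set to the length of the IDR list by signal value, and peaks matched when summits lay within 100 bp, with chance from 100 circular shifts of the summits along each chromosome. Each summit got the first that applied of promoter (within 500 bp of a TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and shares were set against 100000 circular shifts (permutation test, two-sided, Benjamini-Hochberg over 7 classes). A gene was bound when an IDR summit lay within 500 bp of any of its TSSs. For each of 21 lists, bound genes were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists, and with 10000 random draws (with replacement, permutation p two-sided) matched on gene length decile and number of TSSs. In these lists 12 older symbols were looked up under their current names. The 20 motif words were searched on both strands within 50 bp of the summit and in a window of equal length centred 250 bp to a random side, with the exact McNemar test, two-sided, Benjamini-Hochberg adjustment and 1000 bootstrap draws of peaks. X was compared with the 4 large autosomal arms by summits per Mb with an exact binomial test. Where no gene of a list was bound, the limit given is the share that 3 counts would make, and the Wilson interval is in the figure. Values over replicates are mean ± SD with n = 3. The labels call the libraries biological replicates. No replicate was tested as an outlier.

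Genes were named by a fixed rule: noc, elB and osp; the genes with the TSS nearest to the 20 strongest IDR peaks; the 10 protein-coding genes with most IDR summits in the body and 2 kb to each side; up to 4 members with the highest promoter signal for each list past an adjusted p of 0.05 and up to 2 for other lists; and the motifs past that threshold. The genes ush, Adh and lncRNA:CR45303 are named in addition, as the places where such peaks lay, and were chosen after their values were seen, as was Hr3, which shares a TSS with CG46321. A gene that the rule selects is not reported here.

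Alternatives were summit distances of 50 and 250 bp, any shared base of the intervals, shorter and longer lists, the 3600 IDR peaks of higher signal, each replicate's own list, IDR peaks found in both others when a replicate was left out, TSS distances of 250 and 1000 bp, gene bodies with 2 kb, other flanks and windows for motifs, and other divisions by signal. A replicate left out in this way had still contributed to the pooled call and its signal, so these sets are a stricter filter of the IDR peaks. Chosen after the data were seen were local shifts of 5 to 100 kb, IDR peaks found in all 3 replicates, motifs at promoter and other summits, shuffled motif letters, coding sequence without precedence of promoters, and the 6338 genes with a pooled peak near a TSS as background. The methods were tested on simulated data of the size of the IDR list: a planted promoter share of 39.5% was recovered as 39.9%, 4% of 50 unchanged sets passed a permutation p of 0.05, a planted overlap of 69.0% came out as 69.3%, all of 100 planted gene lists and 5% of 100 unplanted lists were called, and a planted motif share of 20.2% was recovered. The same word, unplanted, came out at 1.2 times its flanks in place of 1 (p = 0.720, exact McNemar test). Apart from what was planted, the simulated summits were spread evenly, genes were bound independently and motif windows lay at random positions. Clustered peaks, neighbouring genes that share a summit and a GC share that differs between summits and flanks were therefore not covered by these error rates. Full recovery of the planted gene lists holds only for the list size and the share of bound genes that were planted. It does not give the power of the test for shorter lists or smaller differences, or after adjustment over the lists. A list that did not pass may therefore still differ from other genes.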

Results

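Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map a GFP-tagged form of the zinc finger protein Noc in the genome of whole Drosophila melanogaster larvae. No untagged larvae or other GFP fusion were analysed here, so a peak, or a gene called bound, is not by itself proof of Noc binding. The gene noc (no ocelli, FBgn0005771) is known from the development of the ocelli, the legs and the tracheae, and elB (elbow B) is its neighbour and paralogue. The line carried noc with GFP at the C terminus, and the precipitation used an antibody against GFP. The 3 libraries were biological replicates of 1 group with males and females pooled, so the comparisons were between replicates, between annotations and shifted positions, and between gene lists. The labels give the larvae an age of 48 days, which is copied as given and is long for a larva. The peak lists held 30000 peaks for each replicate, 30000 for the pooled libraries and 7201 after the authors' threshold on the irreproducible discovery rate (IDR), a measure of how alike peaks rank in replicates. These 7201 are the peaks of the pooled list with the highest signal. Peak lists hold no read totals, so sequencing depth is unknown, and the Wilson 95% intervals given below cover counting error over peaks or genes only.

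The strongest peaks lay at cbt, CG11050, Ugalt, Acsf2 and CG14100. The IDR peak with the highest signal value (7897) spanned 2L from 478768 to 482169 (dm6), in an intron of ush, and its summit was 1375 bp upstream of the start site of cbt, which encodes the zinc finger factor Cabut. The next peaks lay in an intron of CG11050 (signal 7634, summit at 2L 6612708), 33 bp upstream of Ugalt, a UDP-galactose transporter gene (signal 6706, summit at X 2703885), 374 bp upstream of Acsf2 (signal 5847) and 91 bp upstream of CG14100 (signal 5581). Genes for the glycolytic enzymes Gapdh2 (signal 4869, 161 bp upstream) and Eno (signal 4424, 189 bp upstream) followed, as did those for the bZIP factor Atf3 (signal 4557, 207 bp upstream) and for GAGA factor, Trl (signal 4175, in an intron). The peak at rank 18 lay in an intron of the ecdysone-induced receptor gene Hr3, whose start site nearest to it, 7863 bp away, is shared with CG46321. The other genes nearest to the 20 strongest peaks were lncRNA:CR44619, gish, CG32772, Pdrg1, mRpL41, CG18428, CG10165, CG1635, for and Fkbp14. Of these 20 summits, 13 were promoter summits and 6 intronic, and all 20 were among the 100 highest-ranked peaks of every replicate.

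The locus of noc itself was among those with the most IDR summits around a protein-coding gene. The gene spans 2L 14490859 to 14494019 on the plus strand, and 20 IDR summits fell in it or within 10 kb, more than for 99.9% of protein-coding genes. The replicates' own lists of the same length placed 16.0 ± 1.00 summits there (SD, n = 3). The strongest of them (signal 3498, rank 35) had its summit at 2L 14497092, downstream of the gene in an exon of lncRNA:CR45303, and a peak of signal 1080 covered the noc promoter with its summit 14 bp upstream of the start site. Of the 20 IDR summits, 10 lay in a single wide interval (2L 14498168 to 14503524), so they are not 20 separate peaks. Whether the tagged noc of this line adds copies of the locus was not tested, and the control alignment was not analysed. A higher copy number therefore cannot be told apart from dense binding as a source of the counts at noc. The region of elB (2L 14390628 to 14409549, minus strand) held 12 IDR summits, most of them intronic, with 8, 14 and 11 in replicates 1, 2 and 3, at percentile 99.4 of protein-coding genes and percentile 95.8 among genes of similar length. The gene osp (outspread, 2L 14599196 to 14689340), further along the arm, held 13 summits in it or within 10 kb, with 11.7 ± 3.79 per replicate. Its strongest peak (signal 2282, summit at 2L 14613783) lay in an osp intron, upstream of the nested gene Adh for alcohol dehydrogenase. Among IDR peaks found in both other replicates when replicate 1, 2 or 3 was left out, the counts were 12, 10 and 12 at noc, 6, 5 and 5 at elB, and 7, 6 and 9 at osp.

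**Figure D1:**
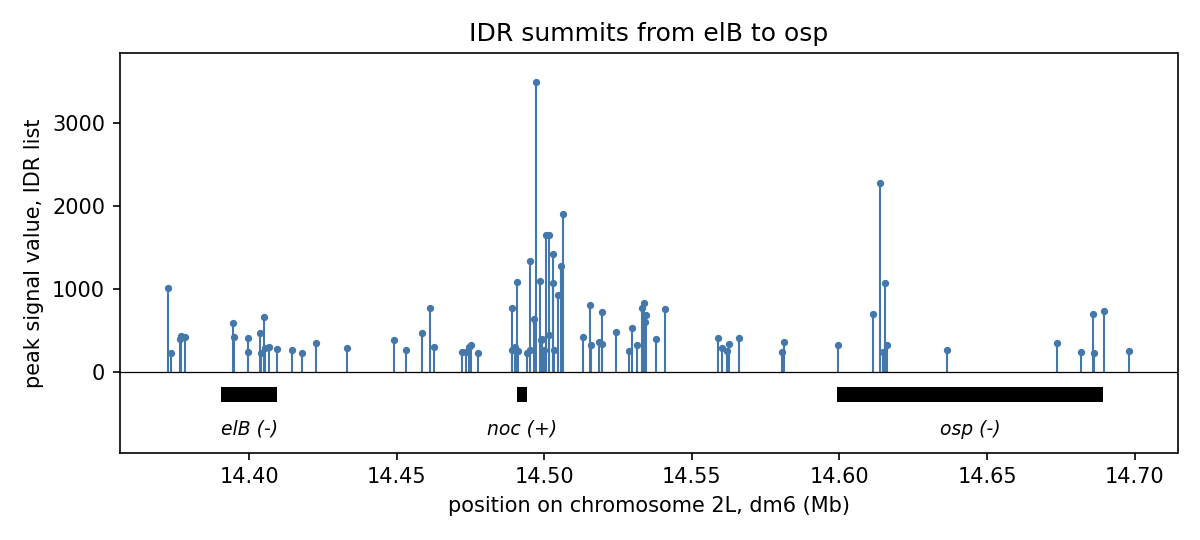
Signal value of each IDR summit (vertical axis, the authors' units) against position on 2L in Mb (dm6), from elB to osp, with gene bodies as black bars and strand in parentheses. The densest group of summits lies at noc and downstream of it, with the highest at a signal of 3498.

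The genes sbb, shn, Eip75B, Pdp1 and bun held the most summits. Counting the gene body and 2 kb to each side, sbb (scribbler), a gene for a nuclear corepressor, held 26 IDR summits (26.3 ± 1.53 per replicate, SD, n = 3). It was followed by shn (schnurri), a zinc finger factor of Dpp signalling, with 22 (27, 22 and 26 in replicates 1, 2 and 3). The ecdysone-induced receptor gene Eip75B, the bZIP gene Pdp1 and bun held 19 each, and the homeodomain gene hth held 18. Tlk held 17, px 16, and CG12535 and CHES-1-like 15 each. Eip75B differed most between the lists, with 16, 31 and 16 summits in replicates 1, 2 and 3. Gene length enters these counts: per 10 kb, CHES-1-like held 4.83 summits and hth 1.32. In all, 5874 of 13945 protein-coding genes (42.1%) held a summit and 57 held 10 or more.

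Of the 7 annotation classes, promoters alone held more summits than shifted positions, and coding exons held almost none. Of the IDR summits, 49.0% lay within 500 bp of an annotated transcription start site (Wilson 47.8% to 50.1%), against 13.6% for summits shifted along their chromosomes. The replicate lists gave 48.3% ± 3.98 (SD, n = 3). Coding exons away from start sites held 15 summits, or 0.208% (Wilson 0.126% to 0.343%), against 13.1% for shifted summits, a share 62.7 times lower. Summits were 3.97 times rarer than shifted ones in 3' UTRs (1.26%) and 2.88 times rarer between genes (9.51%). Introns held 38.6% of summits against 39.3%, 5' UTRs 0.639% against 0.776%, and other exons 0.764% against 0.815%, none of which passed the test. Against local shifts of 5 to 100 kb, chosen after the data were seen, 5' UTRs passed as rarer too (0.998% for shifted summits, permutation adjusted p = 0.00839).

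For promoters, 3' UTRs, coding exons and intergenic sequence the permutation p was 2e-05, the smallest that 100000 two-sided shifts can give, with an adjusted p of 3.5e-05 over 7 classes. With promoters no longer taking precedence, a setting chosen after the data were seen, 97 summits (1.35%) lay in any coding sequence, against 17.1% for shifted summits, a 12.7-fold shortfall in place of 62.7-fold. Introns were more common than in shifted summits in the list of replicate 2 alone (41.9%, permutation adjusted p = 0.0280).

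**Figure D2:**
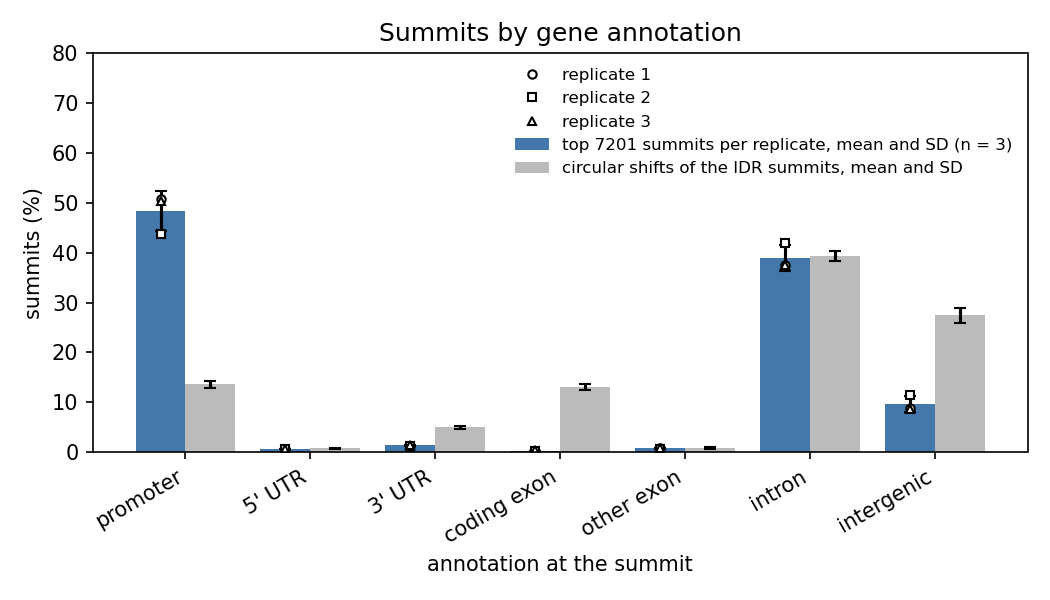
Share of summits in each annotation class (percent), as the mean and SD of the 3 replicates' own lists with each replicate as a point, beside the mean and SD of circular shifts of the IDR summits. Promoters stand at 48.3% against 13.6%, and coding exons are close to 0.

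Genes for cytosolic ribosomal proteins stood out among the 21 gene lists, while genes for cuticle proteins and chemoreceptors were nearly free of promoter peaks. Of 93 ribosomal protein genes, 69 (74.2%, Wilson 64.5% to 82.0%) had an IDR summit within 500 bp of a start site, against 24.2% of other protein-coding genes (adjusted p = 1.49e-22, Fisher's exact test, two-sided). RpL34b (signal 1494), RpL32 (929.7) and RpL7 (875) were among those with the strongest of these peaks. The replicates gave 69.9% ± 1.08 (SD, n = 3). The larval cuticle protein list takes genes by their Lcp and Cpr symbols and not by the stage at which they are used. Of its 85 genes, 2 (2.35%) had such a peak, Cpr67Fb (signal 291) and Cpr73D (268.8), with adjusted p = 2.19e-07 by Fisher's exact test. None of 119 odorant and gustatory receptor genes did, which allows a share of up to 2.52%, the limit of 3 counts (adjusted p = 4.01e-14, Fisher's exact test). These 3 lists kept their direction and their side of the threshold under all 12 alternatives run. Fisher's exact test treats genes as independent, and so do random lists of matched genes. Neighbouring genes can share a summit, so the p-values of both may be too small for lists with genes side by side.

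Genes of the EGF receptor pathway, of the ecdysone response and of the fat body, and genes for corepressors, were bound more often than other genes, a difference that did not pass the threshold against random genes of like length and number of start sites. In the EGF receptor pathway 11 of 20 genes (55.0%) had a promoter peak, led by the ligand genes Krn (signal 1086) and spi (852), Ras85D (566) and the inhibitor gene aos (466), with adjusted p = 0.0159 by Fisher's exact test. Of the corepressors, 6 of 8 (75.0%) did, with gro (signal 1358), Sin3A (754), ebi (690.7) and Gug (372) in front (adjusted p = 0.0159, Fisher's exact test). The ecdysone response list had 12 of 24 genes, led by Eip75B (signal 2122), E23 (1870), usp (453) and tai (448), with adjusted p = 0.0253 (Fisher's exact test). The fat body list had 8 of 15 (53.3%), led by Hnf4 (signal 1025), Apoltp (744), FASN1 (639) and bmm (609), with adjusted p = 0.0460 (Fisher's exact test). Against random lists matched on gene length and number of start sites, none of these 4 calls remained (permutation adjusted p = 0.134, 0.156, 0.653 and 0.409). The share of the EGF receptor pathway was 2.25 times that of other genes (1.40 to 3.03, from its Wilson interval) and 1.77 times that of the matched lists (1.1003 to 2.386, unadjusted permutation p = 0.0384). For corepressors the fold went from 3.06 (1.67 to 3.79) to 2.08 (1.14 to 2.58), for the ecdysone response from 2.04 (1.28 to 2.80) to 1.22 (0.768 to 1.68), and for the fat body from 2.18 (1.23 to 3.07) to 1.48 (0.836 to 2.09). The matched genes were bound more often than other genes, at 31.1%, 36.0%, 40.9% and 36.0% in that order, and the lists are short. Why the calls ended was not tested, since the kind of test changed as well. The calls were lost under 9 to 11 of the 12 alternatives. Without replicates 1, 2 and 3 in turn the share was 25%, 40% and 20% for the EGF receptor pathway, 37.5%, 62.5% and 37.5% for corepressors, 29.2%, 33.3% and 29.2% for the ecdysone response, and 33.3%, 40% and 40% for the fat body, and corepressors without replicate 2 alone passed (adjusted p = 0.0395, Fisher's exact test). Those sets hold 3925, 4901 and 4266 of the 7201 IDR peaks, so fewer genes of any kind have a promoter peak in them. The share of cytosolic ribosomal protein genes fell as well, to 52.7%, 60.2% and 55.9%.

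The remaining 14 lists did not pass Fisher's exact test. Several patterning lists had shares near or below that of other genes. In the eye-antennal disc and ocelli list 5 of 30 genes had a promoter peak, led by hth (signal 452) and so (322), in the leg and wing list 6 of 32, led by bowl (1434) and hth, and among Hox genes and cofactors 2 of 14, hth and cad (369). The Hedgehog list had 3 of 14, led by slmb (441) and fu (253), and the Notch list 6 of 24, led by numb (2497) and neur (1146). Lists with higher shares were the tracheal system, with 10 of 25 genes, led by tkv (1085) and noc (1080), the Wingless pathway, with 9 of 24, led by sgg (1923) and Apc (531), and the Dpp pathway, with 8 of 21, led by shn (1572) and tkv. The Polycomb and trithorax list had 9 of 23, led by ph-p (3734) and brm (2009), and the heat shock list 6 of 15, led by Hsp27 (2366) and Hsp26 (854). Tissue markers gave 3 of 20 for neurons and glia, with elav (2796) and moody (1585) in front, and 5 of 20 for muscle, with sls (687) and Mef2 (533). Digestive enzymes had 15 of 39 (38.5%), led by Jon99Cii (820) and thetaTry (645), and antimicrobial peptides 0 of 14, which allows a share of up to 21.4%. Against matched random lists the digestive enzymes were above (mean of the random lists 6.42 genes, permutation adjusted p = 0.00840) and the neuronal and glial markers below (9.15 genes, permutation adjusted p = 0.0269). Many of the digestive enzyme genes lie side by side, so the p-value for that list may be too small. The replicates' own lists had 13, 8 and 16 of the digestive enzymes, and 20.5%, 28.2% and 15.4% of them had a peak without replicates 1, 2 and 3. The latter sets hold fewer peaks, so the share of all genes is lower in them too. Among genes with a pooled peak at a start site, chosen as background after the data were seen, 15 of 29 digestive enzymes (51.7%) had an IDR summit, against 54.0% of the others.

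**Figure D3:**
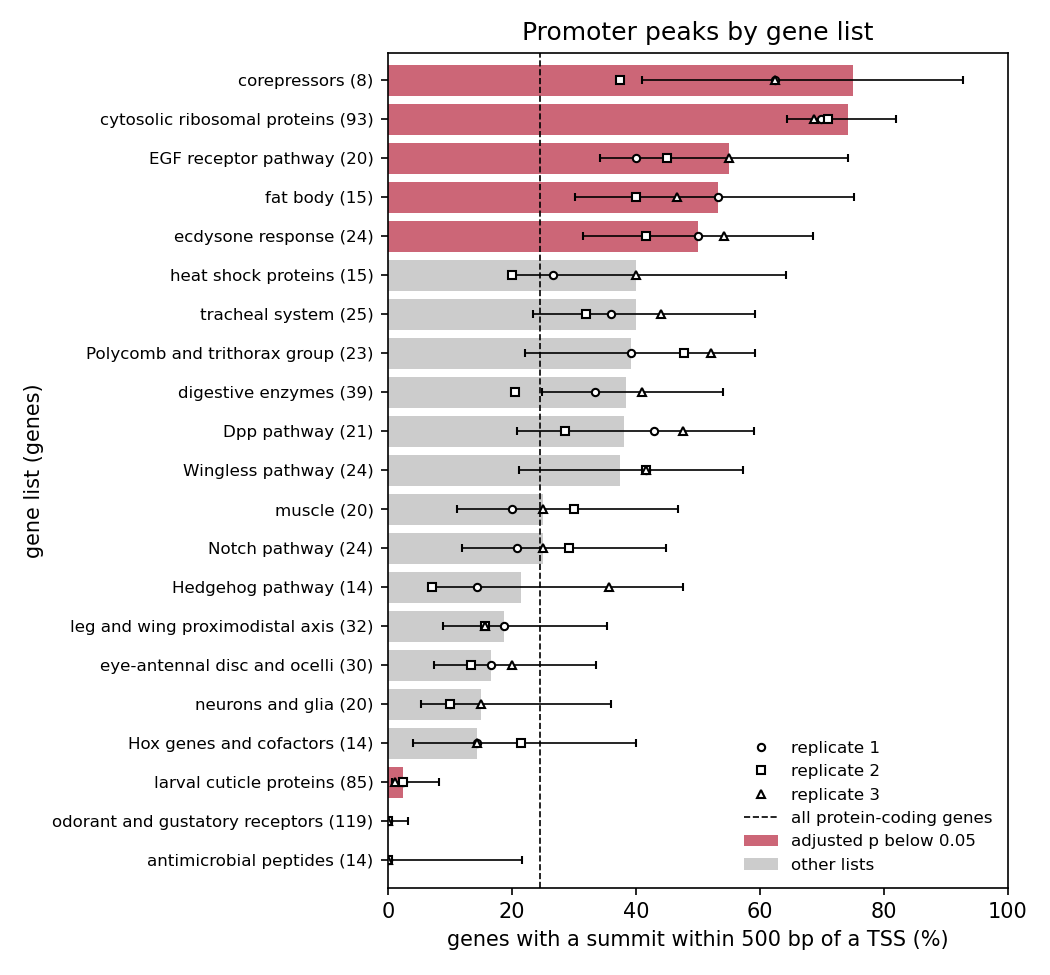
Share of each list's genes with an IDR summit within 500 bp of a start site (percent, bars, with Wilson 95% intervals) and the same share in each replicate's own list (points), list sizes in parentheses and the share of all protein-coding genes (24.5%) as a dashed line. Coloured bars passed an adjusted p of 0.05, as did the odorant and gustatory receptors, whose bar has a length of 0.

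At the summits, the homeodomain and GATA words were more common than in flanking sequence, and 8 of the other words were rarer. For homeodomain and GATA, words with the same letters in shuffled order had similar ratios, as given below. The 8 rarer words lay inside the ranges of their shuffled words too. The homeodomain core TAATTA occurred within 50 bp of 9.72% of summits and in 5.80% of flanks of the same length, a ratio of 1.67 (bootstrap 95% interval 1.49 to 1.87, replicates 1.65 ± 0.119, SD). The GATA word WGATAA occurred at 22.2% of summits against 16.2%, a ratio of 1.37 (1.28 to 1.47, replicates 1.34 ± 0.0378). The other 8 motifs past the threshold were rarer at summits: GAGA factor (ratio 0.741), the CLAMP-like CA repeat (0.679), the E-boxes CAGCTG (0.821) and CACGTG (0.531), the Sp/KLF GC box (0.558), Brinker/Mad (0.669), Scalloped (0.806) and Pho (0.799). Among IDR peaks found in both other replicates, Pho missed the threshold without replicate 2 (ratio 0.868), where Zelda (0.675), the nuclear receptor half-site (0.659), the Ftz-f1 site (0.333) and Grainyhead (0.231) passed it as rarer. The Ftz-f1 and Grainyhead words occurred at only 0.139% and 0.111% of all IDR summits, so their ratios rest on few peaks. The E-box CATCTG (0.838 in the IDR list, not past the threshold) passed it as rarer whichever replicate was left out (0.635, 0.75 and 0.682 without replicates 1, 2 and 3). In the replicates' own lists Pho missed the threshold in replicate 3 (0.972), and CAGCTG in replicates 1 (0.847) and 3 (1.01). Scalloped missed it in the stronger IDR peaks (0.783), and both at promoters (0.792) and away from them (0.835). The GC share was 36.5% at summits and 42.0% in flanks, with 36.6% ± 1.35 and 42.1% ± 0.347 over the replicates (SD).

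The exact McNemar test, two-sided, gave adjusted p = 7.55e-20 for GATA and 1.98e-17 for the homeodomain word over 20 motifs. Set against words made of the same letters in shuffled order, a comparison chosen after the data were seen, the homeodomain word lay at percentile 53.8 of its 13 shuffled words and GATA at percentile 70.6 of 119. The median ratio of the shuffled words was 1.67 for the homeodomain word and 1.32 for GATA, against 1.67 and 1.37 for the words themselves. Their excess over flanks was thus close to that of words with the same letters, and gives no support for the words beyond their letters. It cannot argue against the words either, because some shuffled words hold part of them. ATATTA (1.77) and ATTATA (1.72) hold ATTA, as TAATTA does, and shuffles of WGATAA include words with GATA. The shuffles were too few for a single motif to pass an adjusted p of 0.05 (0.199 at best over 20 motifs, permutation), so the p-values do not decide whether any motif stands apart from its letters.

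**Figure D4:**
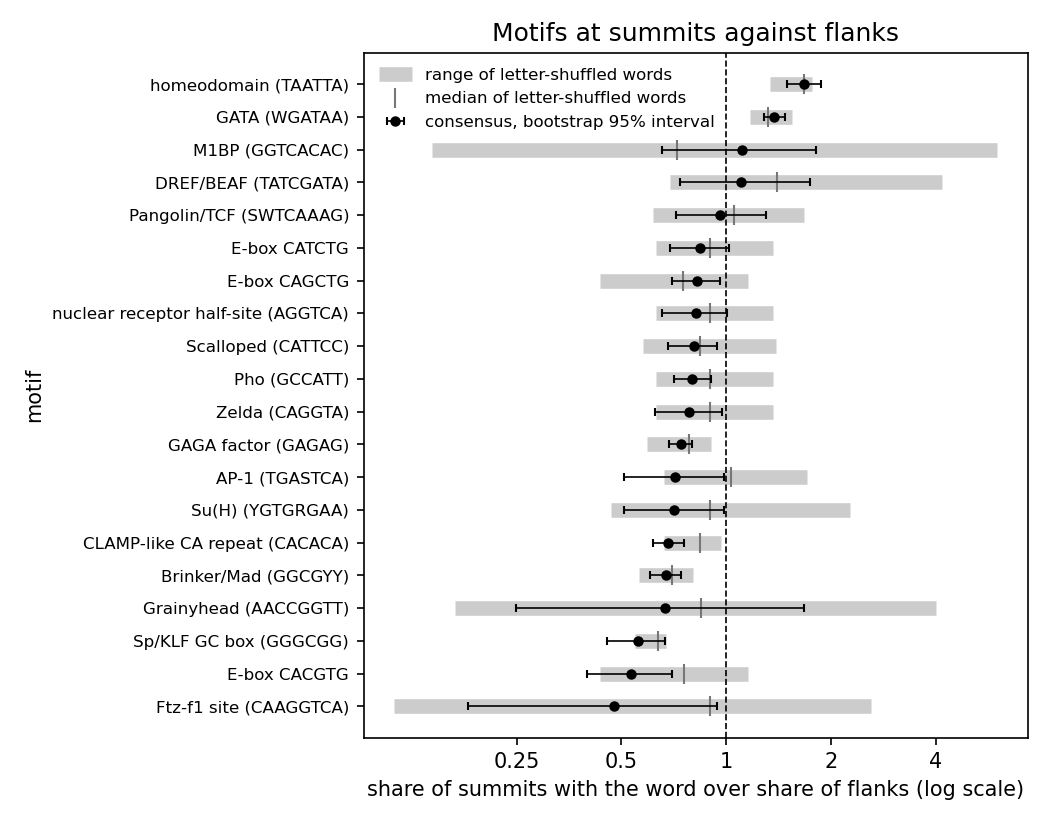
Share of IDR summits with each word within 50 bp, divided by the share of flanking windows (log scale, points with bootstrap 95% intervals), beside the range (grey bars) and median (ticks) of words with the same letters shuffled. GATA at 1.37 and the homeodomain word at 1.67 lie inside the ranges of their shuffled words.

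Replicates shared most of their strong peaks, and replicate 2 stood further from the other replicates. With 7201 peaks taken from the top of each list, 70.8% were shared by replicates 1 and 3, 61.2% by 1 and 2, and 55.5% by 2 and 3, within 100 bp between summits. Shifts along the chromosomes gave 1.11% on average and at most 1.96%. All 3 replicates held 3580 of the IDR peaks (49.7%, Wilson 48.6% to 50.9%), and 144 (2.00%) were in the top of none. Replicate 1 held 82.5% of the IDR peaks, replicate 2 68.9% and replicate 3 78.6%. Across the 5663 IDR peaks present in all 3 full lists, which are not independent of each other, the rank correlation (Spearman) was 0.786 between replicates 1 and 3, 0.685 between 1 and 2 and 0.541 between 2 and 3.

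**Figure D5:**
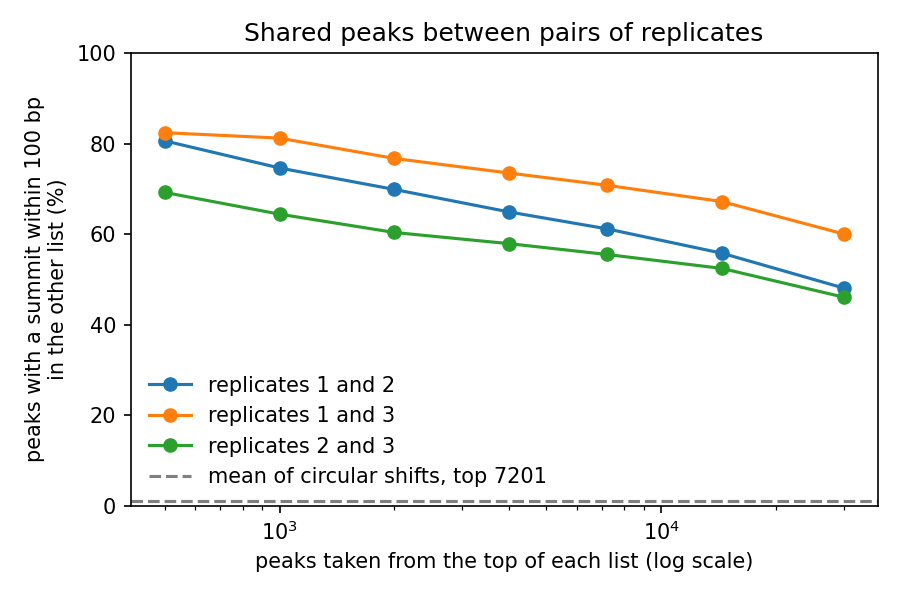
Share of peaks with a summit within 100 bp in the other replicate's list (percent) against the number of peaks taken from the top of each list (log scale), for each pair of replicates. Replicates 1 and 3 shared 82.4% at 500 peaks and 70.8% at 7201, above both pairs with replicate 2 throughout.

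Stronger peaks were more often at promoters and more often found in every replicate. Of the 1800 IDR peaks with the highest signal, 53.1% were at promoters, against 46.0% of the 1800 with the lowest (p = 2.28e-05, Fisher's exact test, two-sided). All 3 replicates held 91.6% of the former (Wilson 90.2% to 92.8%) and 6.39% of the latter (5.35% to 7.61%). The replicate lists used there end at the length of the IDR list, so the weakest IDR peaks lie near that limit and tend to fall below it. In the full lists, used after the data were seen, the shares were 92.9% (91.7% to 94.0%) and 67.1% (64.9% to 69.2%). The signal comes from the pooled libraries, so it is not independent of the replicates.

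The X chromosome carried nearly as many summits per Mb as the autosomal arms. There were 51.1 IDR summits per Mb on X and 53.3 to 58.5 on 2L, 2R, 3L and 3R, a ratio of X to the 4 arms together of 0.930 (p = 0.0225, exact binomial test, two-sided). The replicates gave 0.936 ± 0.0596 (SD, n = 3), with 0.886, 1.00 and 0.920 for replicates 1, 2 and 3, so the ratio was not below 1 in every replicate. Peaks cluster, so the exact p is too small.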

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

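Of the tests in this part, that of coding exons by peak rank was chosen only after the result was seen, as were the local shifts, the division of summits by GC share, the gap among the 500 strongest peaks and the comparison of snRNA and snoRNA genes. The list of pooled peaks below the IDR threshold, which no comparison above used, held 22799 peaks, of which 24.1% (Wilson 23.5% to 24.6%) had a summit within 100 bp in the full lists of all 3 replicates. The pooled list was called on the same 3 libraries, so this share is not independent of them. Of these weaker peaks 28.3% lay at promoters and 1.96% in coding exons.

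Summits in coding exons were rare at 0.208%. Base composition is argued against as the whole cause, since random positions with the same GC share in the surrounding sequence had 7.08% in coding exons, below the 13.1% of shifted summits but far above the observed share. A peak caller or threshold that leaves out coding exons cannot be told apart as a cause. The share rose from 0.3% in the 10000 strongest pooled peaks to 3.15% in the 10000 weakest, a factor of 10.5, as a limit on signal would give, but stayed below that of shifted summits. No biological explanation was tested, since the series holds 1 group, and it also remains open whether any tagged factor would give the same share.

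Summits gathered near transcription start sites. Gene-dense regions are argued against as the whole cause of the 49.0%, as the highest of 1000 local shifts of 5 to 100 kb gave 19.7%. Capture of DNA at highly transcribed genes, whatever the tagged protein, cannot be told apart from binding of Noc: ribosomal protein genes were bound far more often than other genes, but tRNA genes, at 25.9% (Wilson 21.2% to 31.2%) against 24.5% of protein-coding genes, gave p = 0.582 (Fisher's exact test). Genes for snRNAs (2 of 32, 6.25%) and snoRNAs (23 of 269, 8.55%) were bound less often than protein-coding genes, with adjusted p of 0.0159 and 5.06e-11 (Fisher's exact test over 5 classes of genes), which goes against this explanation. They do not settle it, since no expression values were used here, many genes for tRNAs and snRNAs have near-identical copies, and snoRNAs are often made from introns of other genes. A comparison with untagged larvae or another GFP fusion could tell them apart, and none was analysed here.

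Replicate 2 shared fewer peaks with replicates 1 and 3 than those did with each other, by 12.4 percentage points. By the test set beforehand, weaker enrichment or lower depth was argued against as the whole cause. The gap among the 1000 strongest peaks was 11.7 points (bootstrap 95% interval 9.42 to 13.9), above the bound of 8.30. Among the 500 strongest peaks the gap was 7.5 points (4.80 to 10.2), below that bound. There 80.6% were shared by replicates 1 and 2, 82.4% by 1 and 3 and 69.2% by 2 and 3. The outcome thus depends on the number of peaks taken, and a weaker library can also reorder its strongest peaks. Weaker enrichment or lower depth therefore remains open as a cause, whole or in part. Replicate 2 did have fewer peaks at the ceiling of its q value, 3827 against 11431 and 12058. Base composition cannot be told apart as part of the cause. The median GC share at the summits of replicate 2 differed by -1.99 points from that of replicate 1, between the bounds set beforehand. With the summits divided into 3 groups by GC share, the gap was 8.12 points in the group with the lowest GC and 13.2 and 16.4 in the others. The groups were not of equal size, and the lowest held 2306, 2858 and 1989 peaks of replicates 1, 2 and 3.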

How the results depend on the processing

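The promoter share kept its direction and side of the threshold under all alternatives run (38.0% at 250 bp from a TSS to 60.5% at 1000 bp), as did coding exons, intergenic sequence and the contrast of strong and weak peaks. Mean pair overlap, 62.5%, was 48.2% with summits within 50 bp, 72.7% within 250 bp and 74.1% for shared intervals, and 55.5% to 70.8% leaving out a replicate. IDR peaks in all replicates, 49.7%, became 34.5%, 62.1% and 63.8% under those distances, 72.8% with lists of double length, and 54.5% to 68.1% leaving out a replicate. Introns moved above shifted summits in replicate 2 (41.9%), and against local shifts 5' UTRs passed as rarer, which makes 5 classes in place of 4. The X ratio, 0.930, was 0.886 and 0.920 in the own lists of replicates 1 and 3, both past the threshold of the exact binomial test. The ratio was 0.923 in the stronger IDR peaks and 1.00 in replicate 2, and 0.95 to 1.02 leaving out a replicate, none of these past the threshold. Gene lists past the threshold, 7, were 9 at 1000 bp from a TSS, 3 in the stronger peaks, 4, 3 and 6 in replicates 1, 2 and 3, 5 against matched random lists, 3 in peaks of all 3 replicates, 4 with gene bodies, 3 against genes with pooled peaks, and 3 to 4 leaving out a replicate. Digestive enzymes (48.7%) and antimicrobial peptides (0%) passed it at 1000 bp, digestive enzymes also with gene bodies (64.1%), and the Polycomb and trithorax list in replicate 3 (52.2%). Summits at noc, 20, were 13 in the stronger peaks and 10 to 12 leaving out a replicate, at elB, 12, were 5 and 5 to 6, and at osp, 13, were 5 and 6 to 9. Motifs past the threshold, 10, were 16 with flanks 500 bp away, 16 with windows of 100 bp to each side and 6 at promoters. Shuffled letters gave 0 (1 at an unadjusted permutation p below 0.05), but no single motif could have passed there, so this count decides nothing. CAGCTG reached a ratio of 1.01 in replicate 3 and was lost in replicate 1, with windows of 100 bp (0.934) and at promoters (0.888), where CACGTG (0.618), Scalloped and Pho (0.929) were lost too. DREF/BEAF, 1.103 and not past the threshold, passed it as more common in replicates 1 and 3 (1.87 in both), with flanks 500 bp away (1.87) and with windows of 100 bp (1.54). Away from promoters DREF/BEAF passed it as rarer (0.0909), but only 0.0272% of those summits held the word, so that ratio rests on very few peaks. M1BP, 1.107, passed it as more common in replicate 1 (1.85) and with windows of 100 bp (1.51). Smaller peak sets hold fewer summits by construction, and for the other changes the cause was not tested. The pooled list at the length of the IDR list is the IDR list itself, so that alternative gave no value. No paired analysis was possible because there is 1 group. Depth is unknown, so its limit could not be set.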

Other observations

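The tests in this part were all chosen after the data were seen. Each of 5 further gene lists was compared with other genes and with matched random lists. Of 73 mitochondrial ribosomal protein genes, 30 (41.1%, Wilson 30.5% to 52.6%) had a promoter summit, led by mRpL41 and mRpS10, against 24.4% of other genes (adjusted p = 0.00605 over 5 lists, Fisher's exact test), and 11.01 genes on average in random lists matched on length and number of start sites (permutation adjusted p = 0.0010, from the smallest p the draws can give). Of 12 glycolysis genes 8 did, among them Gapdh2, Eno, Hex-A and Ldh, with adjusted p = 0.00605 by Fisher's exact test but 0.516 against matched lists (permutation). The list was drawn up because Gapdh2 and Eno were among the strongest peaks. Proteasome genes (10 of 32), V-ATPase genes (12 of 33) and cytochrome P450 genes (21 of 85) gave adjusted p of 0.512, 0.255 and 1.00 (Fisher's exact test).

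Chromosome 4 carried 5 IDR summits, where its length alone would give 72.5 (p = 7.71e-25, exact binomial test, two-sided), and the replicates' own lists had 7 ± 2.65 (SD, n = 3). The full pooled list had 22 against 302.1. As for X, the exact p is too small because peaks cluster. This chromosome carries 80 protein-coding genes, 59.3 per Mb against 104.2 over all arms.

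The widest IDR interval of the genome lay downstream of noc, at 2L 14498168 to 14503524 (5357 bp, 10 summits). The second widest (3557 bp, 3 summits, from 14503444 to 14507000) overlapped its end, and the fourth (2833 bp) its start. The interval at cbt was the third widest (3402 bp). As for the summit counts at noc, a higher copy number of the tagged locus cannot be told apart as a source of the wide intervals there.

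Among promoter summits, 63.8% (Wilson 62.2% to 65.4%) lay upstream of the nearest start site, with a median position 79 bp upstream. Of the 2080 words of 6 bases, 329 were more common at summits than in flanks and 733 rarer (adjusted p below 0.05, exact McNemar test). Among words found at 3% or more of summits, those with the highest ratios, ATATTA (1.77) and TTTAAA (1.74), hold no G or C, and the lowest ratios, at any share of summits, were those of CCAGGA (0.369) and AGGACG (0.370).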
